A study of Homo sapiens with 16 samples.

How the data were processed

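The deposited files hold raw UMI counts (a UMI is a tag that marks 1 captured RNA molecule) per gene and cell for the mRNA libraries, and UMI counts per guide array and cell for the guide libraries. Per the submitters' processing notes, reads were aligned to GRCh38 and counted with Cell Ranger 9.0.0, and cells were handled with Seurat 4.1.1. The rule by which the authors kept cells in the guide tables was not given in the sources used here. The smallest count of a cell's top array in those tables was 5 UMIs. The count matrices held 38606 genes, and their rows for guide arrays contained no entries, so array counts came from the guide tables alone. Every cell column of the per-sample tables was matched to its lane, and 0 columns stayed unmatched.

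A cell was given an array when its top array had at least 3 UMIs and at least 3 times the count of the next array, and every cell in the guide tables passed. A stricter assignment (at least 10 UMIs and 5 times the next) kept 2228 of 2483 HAP1 cells and 4158 of 4187 MDA-MB-231 cells. A quality filter planned in advance (at least 2000 UMIs per cell and under 20% mitochondrial UMIs) removed no cell. Total UMIs per mRNA lane were 17920842, 2128119, 18576386 and 17013259 in HAP1 lanes 5 to 8, and 22012767, 21045783, 22048967 and 21366303 in MDA-MB-231 lanes 1 to 4. Median UMIs of the top array per cell were 28, 36, 17 and 28 in those HAP1 lanes and 35, 35, 34 and 33 in those MDA-MB-231 lanes. No doublet caller was run. Cells with UMIs of more than 1 array (14 in HAP1, 10 in MDA-MB-231) passed the rule above and were kept, and doublets of cells with the same array could not be seen in this way.

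Cells are not replicates, so UMI counts were summed over the cells of each class or target within each lane, using lanes with at least 3 such cells. A target was tested with at least 20 cells and at least 2 such lanes. Where a target is said to raise or lower a gene, cells with arrays against that target are meant. Whether lanes of 1 line came from separate cultures or from 1 cell suspension was not given in the sources used here. The p-values of tests over lanes therefore measure only the spread between lanes, which may be technical. Permutations over arrays or targets and the Fisher exact test do not measure that spread. The Fisher exact test treats cells as independent. Tests used edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr) in R 4.3.3 with lane as a block, and 0.05 after Benjamini-Hochberg (BH) adjustment as the threshold for a call. All targets of a line shared 1 fit with the same non-targeting sums, so results for different targets share their controls. The comparison of the lines has no block because no lane holds both.

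DESeq2 1.42.0 and alternative fits (no expression filter, size factors of another kind, no block, each array as its own unit, separate fits per target, stricter assignment, part of the non-targeting arrays, each lane left out) are given beside the main results. The DESeq2 filter on mean counts left 11036 (lncRNA), 9166 (other coding) and 6480.0 (positive control) genes without an adjusted p in MDA-MB-231, 8333 and 8290.0 in the differences between the lines for lncRNA and positive-control arrays, and 0 in the other pooled comparisons, so its counts there rest on fewer genes. Both sums from a lane were compared after removing class means to check the block: the correlation of the same lane's sums was 0.382, 0.342, 0.278 and 0.611 in HAP1 lanes 5 to 8 and 0.699, 0.627, 0.448 and 0.538 in MDA-MB-231 lanes 1 to 4. All were over 0.1, so the block was kept. The highest correlation with a sum of another lane was 0.159, −0.151, 0.210 and 0.0353 in those HAP1 lanes and −0.00335, −0.0339, 0.205 and 0.515 in those MDA-MB-231 lanes.

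Gene lists written before the counts were opened were tested with fry on voom values (limma 3.58.1): 27 lists in the file and the ribosomal proteins by symbol pattern, of which 26 held enough tested genes. The fry p tests whether the members move on balance in 1 direction. It makes no comparison with the genes outside the list. Camera with an estimated correlation between members, and with a preset correlation of 0.01, is given beside it. A camera p compares the list with the other genes. Cell cycle phases were scored with scanpy 1.11.5 on cells thinned to 5000 UMIs, and cells with fewer (140.0 in HAP1, 34 in MDA-MB-231) were left out. Small samples were tested by exact permutation, other permutation tests drew 100000 resamples, and intervals are 95% bootstrap intervals from 2000 draws.

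The methods were tested on simulated counts drawn from the model fitted to the real data, with group effects set to 0 and planted genes moved. Such counts follow the model, so they do not test performance where real counts depart from it. Of 100 genes planted at 2-fold, 89%, 86% and 61% were recovered in HAP1 (lncRNA, other coding, positive control sums) and 77%, 84% and 76% in MDA-MB-231. For 1 target the shares were 56% and 46%. At 1.5-fold they were 56%, 51%, 31% and 21% in HAP1 and 51%, 58%, 50% and 28% in MDA-MB-231. False calls numbered from 2 to 14 per comparison. A list planted at a log2 of 0.2 was called in both lines, with 0 other lists called.

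Genes were named by a rule fixed in advance: targeted genes' own RNA (per line, the 3 largest falls and the 3 with the highest CPM, which is the count divided by the effective library total on a scale common to all samples), the smallest p in pooled comparisons with 1 direction in every lane, the 6 targets per line with most calls, and for the lines the largest fold changes at a mean of at least 100.0 CPM. The same rule was used for the other protein-coding targets, which were added later. One gene that met the rule in the HAP1 positive-control comparison is not reported here. Genes named for other reasons are marked as chosen after their values were seen. Positions are GRCh38.p14 RefSeq. CPM values are means ± SD over lanes, and log2 fold changes are given ± standard error (SE).

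The library names its lncRNA targets by XLOC identifiers, for which no gene name or position was used here. Their own RNA was therefore not tested, and the planned test of genes near the targeted lncRNAs was not run. The guide rows of the matrices and the target gene column of the array table, which repeats 1 placeholder, were left out.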

Results

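The series holds single-cell RNA counts and guide array counts from a pooled RNA knockdown screen in a pair of human cell lines. HAP1 is a near-haploid line from a chronic myeloid leukaemia, labelled bone marrow by the submitters, and MDA-MB-231 is a triple-negative breast adenocarcinoma line. Cells carried a nuclear, doxycycline-inducible RfxCas13d, an RNA-guided enzyme that cuts RNA and leaves DNA untouched. In CaRPool-seq each cell's guide array is read by a barcode together with that cell's own messenger RNA. Cells were transduced at a multiplicity under 0.2 and harvested 3 days after induction. Each line was run in 4 lanes, and each lane gave 1 mRNA and 1 guide library, so the series counts 16 samples. The library held 81 arrays against 27 long non-coding RNAs (lncRNAs), 30 against 10 protein-coding genes, 6 against the common essential genes MYC, MTOR and HSPA9 (here the positive controls), and 10 non-targeting.

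HAP1 contributed 2483 cells and 55638606 UMIs, and MDA-MB-231 contributed 4187 cells and 86473820 UMIs. HAP1 lanes 5, 6, 7 and 8 held 683, 54, 810.0 and 936 cells with 17920842, 2128119, 18576386 and 17013259 UMIs. MDA-MB-231 lanes 1 to 4 held 1046, 1021, 1022 and 1098 cells with 22012767, 21045783, 22048967 and 21366303 UMIs. Median UMIs per cell were 26477, 44152.5, 23219 and 18213.5 in those HAP1 lanes, and 20116, 19923, 20864.5 and 18740.00 in those MDA-MB-231 lanes. HAP1 had 247 non-targeting, 1374 lncRNA-targeted, 767 other protein-coding and 95 positive-control cells. MDA-MB-231 had 362, 2380.00, 1294 and 151 such cells. The most abundant non-targeting array alone supplied 121 of the 247 non-targeting cells in HAP1 and 156 of the 362 in MDA-MB-231. Tests over lanes do not measure differences between non-targeting arrays.

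CHCHD1, a component of the small mitochondrial ribosomal subunit, lost most of its RNA in MDA-MB-231 cells that carried its arrays: log2 fold change −2.22 ± 0.14 (64.4 ± 23.4 against 295 ± 27.7 CPM, n = 4 lanes, lower in 4 of 4, 21.4% left). In HAP1 it fell by 1.14 ± 0.15 log2 units (103 ± 29.5 against 224 ± 22.5 CPM, n = 3 lanes). The kinase gene MTOR fell in HAP1 (−1.34 ± 0.31, 15.1 ± 9.39 against 41.3 ± 4.65 CPM). The RNA-binding protein gene HNRNPR fell in HAP1 (−0.49 ± 0.14, lower in 3 of 3 lanes) and in MDA-MB-231 (−0.74 ± 0.16, lower in 3 of 4 lanes). The sterol-binding protein gene OSBP fell in MDA-MB-231 (−1.04 ± 0.31; 11.8 ± 5.36 against 25.1 ± 3.71 CPM). The mitochondrial chaperone gene HSPA9 showed no fall there (0.05 ± 0.19; 115 ± 41.4 against 111 ± 2.50 CPM). With edgeR and BH over the targeted genes alone, adjusted p was 1.18e-35 for CHCHD1, 2.30e-05 for HNRNPR, 0.00240 for OSBP and 0.0539 for MTOR (−1.0 ± 0.44) in MDA-MB-231. In HAP1 it was 1.39e-10 for CHCHD1, 0.000133 for MTOR, 0.00267 for HNRNPR and 0.0811 for the adhesion gene CLMP (−0.91 ± 0.42).

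Over the list alone, 3 of 10 tested targeted genes were called lower in HAP1 and 3 of 11 in MDA-MB-231. Adjusted with edgeR and BH over all genes, CHCHD1 (1.12e-07) and MTOR (0.0160) passed in HAP1, and CHCHD1 (8.38e-33) and HNRNPR (0.00271) in MDA-MB-231. HNRNPR in HAP1 (0.556) and OSBP (0.385) did not. Without lane 7 or 8 the all-gene adjusted p of MTOR in HAP1 was 0.367 or 0.209. That of HNRNPR in MDA-MB-231 was 0.122, 0.0536 and 0.169 without lanes 1, 2 and 3. Both counts over the list stayed at 3 with no replicate block. The HAP1 count was 4 without lane 7, and the MDA-MB-231 count 4 without lane 1 and 2 without lane 2. Chosen after its value was seen, the nuclear receptor gene NR2C2 was higher with its own arrays in MDA-MB-231 (1.01 ± 0.30, adjusted p = 0.00240 by edgeR and BH over the list, 0.295 over all genes), and the transcription factor gene MYC was not lower (0.46 ± 0.31). In HAP1, HSPA9 (18 cells), MYC (12 cells) and KAZALD1 were not tested, and in MDA-MB-231 KAZALD1 and PRSS12 (1 against 28 UMIs) were not tested. The libraries count 3′ ends, so an RNA cut upstream can still be counted. Positions are CHCHD1 chr10:73782048-73783652, MTOR chr1:11106535-11262551, HNRNPR chr1:23304688-23344284, OSBP chr11:59574398-59615774, HSPA9 chr5:138553756-138575401, NR2C2 chr3:14947583-15049273 and MYC chr8:127735434-127742951.

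**Figure D1:**
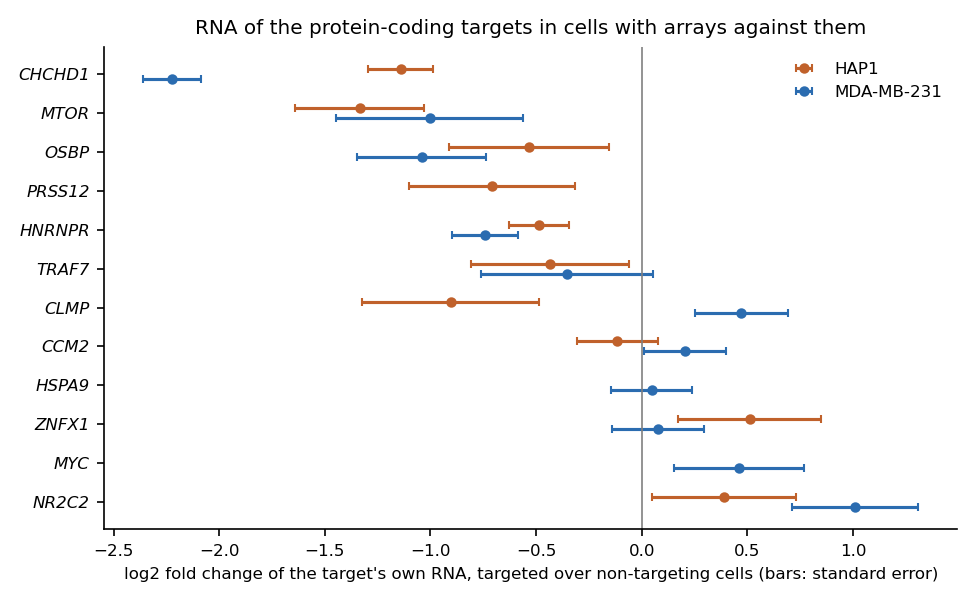
Log2 fold change of each targeted protein-coding gene's own RNA in cells with its arrays over non-targeting cells, by line. Points are edgeR estimates and bars their standard errors.

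Many genes differed between the lines. In non-targeting cells HAP1 expressed the oncofetal heparan sulfate proteoglycan gene GPC3 at 283 ± 78.6 CPM against 0 UMIs in MDA-MB-231 (at least 883-fold), and also the ubiquitin hydrolase gene UCHL1 (log2 8.15 ± 0.25; 391 ± 58.5 against 1.37 ± 2.74 CPM) and the cadherin gene CDH2 (7.63 ± 0.24; 212 ± 34.1 against 1.02 ± 1.22 CPM). NPW (2132 against 1 UMIs), APOE (1651 against 3), EEF1A2 (8.51 ± 0.27), TPM2 (7.57 ± 0.20), BST2 (6.17 ± 0.21), IGFBP2 (4.52 ± 0.15), CKB (3.62 ± 0.13), MDK (3.52 ± 0.14) and APOC1 (3.27 ± 0.13) were also higher in HAP1. MDA-MB-231 expressed the polyubiquitin gene UBB (869 ± 98.4 CPM, at least 1455-fold), ADIRF (495 ± 90.6 CPM, at least 824-fold) and the proteoglycan gene SRGN (486 ± 24.7 CPM, at least 823-fold) where HAP1 had 0 UMIs. G0S2, a lipolysis inhibitor, was at 2557 ± 31.4 CPM in MDA-MB-231 (log2 −11.83 ± 0.27). C19orf33 (10133 against 2 UMIs), CAVIN3 (2064 against 1), IGFBP7 (1414 against 1), IFITM3 (2324 against 2), H2AJ (1990.0 against 2), UBE2C (2722 against 3), ARHGDIB (1477 against 2) and CAPG (1471 against 3) were likewise higher in MDA-MB-231.

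With edgeR and BH, 3463 genes were called higher in HAP1 and 3492 higher in MDA-MB-231 of 10442 tested (n = 4 lanes each, no block; 2597 and 3114 with DESeq2). Adjusted p for the genes named was 1.46e-31 or less. Of the marker genes listed for HAP1, 8 of 9 tested were higher in HAP1, and of those for MDA-MB-231, 16 of 17 were higher in MDA-MB-231. Of other markers tested, 6 were luminal epithelial (2 higher in HAP1, 4 in MDA-MB-231), 2 haematopoietic (1 higher in each line) and 2 fibroblast (both higher in HAP1). Line and lane cannot be separated here, as no lane held both lines.

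In MDA-MB-231 cells with lncRNA-targeting arrays as a class, 2 histone and 2 keratin genes were among the higher genes with the smallest p. H1-2, a linker histone gene in the chromosome 6 histone cluster (chr6:26055740-26056470), rose by 0.97 ± 0.06 log2 units (443 ± 36.1 against 223 ± 32.3 CPM, n = 4 lanes, higher in 4 of 4, adjusted p = 2.29e-13 by edgeR and BH). The core histone gene H2AC6 (1.06 ± 0.10; 149 ± 13.9 against 70.5 ± 21 CPM), the keratin genes KRT81 (1.01 ± 0.07; 249.8 ± 29.2 against 122 ± 23.2 CPM) and KRT7 (0.57 ± 0.07; 181 ± 14.0 against 121 ± 17.1 CPM) and the unannotated gene ENSG00000290032 (0.96 ± 0.07; 198 ± 15.1 against 101 ± 19.1 CPM) also rose. So did the autophagy receptor gene SQSTM1 (0.42 ± 0.04) and the antioxidant enzyme gene NQO1 (0.34 ± 0.04; 611 ± 30.6 against 484 ± 45.5 CPM), both targets of the oxidative stress factor NRF2. The stress cytokine gene GDF15 (1.62 ± 0.21; 20.2 ± 2.52 against 6.30 ± 4.01 CPM) and the acute-phase gene SAA1 (2.78 ± 0.36; 8.27 ± 3.34 against 1.12 ± 1.09 CPM) rose from low levels. AMIGO2 (0.79 ± 0.10), the glycosyltransferase gene EXT1 (0.33 ± 0.04) and the snoRNA host gene SNHG25 (0.40 ± 0.05) completed the 12 higher genes with the smallest p. The median mitochondrial share of UMIs was 1.25% in these cells and 1.18% in non-targeting cells.

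Among the lower genes with the smallest p, the ribosomal protein genes RPS2 (−0.24 ± 0.03; 2486 ± 149.7 against 2937 ± 148 CPM, adjusted p = 5.93e-07 by edgeR and BH), RPLP1 (−0.18 ± 0.02), RPL12 (−0.18 ± 0.03), RPL41 (−0.16 ± 0.02) and RPS7 (−0.18 ± 0.03) were lower in 4 of 4 lanes. So were the elongation and initiation factor genes EEF1D (−0.25 ± 0.04) and EIF3K (−0.25 ± 0.04) and the mitochondrial ribosomal gene MRPL52 (−0.23 ± 0.03). The tetraspanin gene CD9 (−0.45 ± 0.06; 98.1 ± 10.2 against 134 ± 14.7 CPM), PDAP1 (−0.39 ± 0.05; 165 ± 10.2 against 217 ± 19.1 CPM), the histone variant gene H2AZ1 (−0.22 ± 0.03) and the nuclear transport GTPase gene RAN (−0.23 ± 0.04) fell as well. The adjusted p of these genes was 0.000176 or less by edgeR and BH.

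Of 12650.0 genes tested in this comparison, 92 were called higher and 242 lower with edgeR and BH (1675 at unadjusted p under 0.05), and 29 and 300.0 with DESeq2, which left 11036 genes without an adjusted p. In place of 334, 29 genes were called with no replicate block. With each array as its own unit and no lane term, 3 were called. Leaving out lane 1, 2, 3 or 4 gave 179, 213, 196 or 191 calls. The 24 genes named above kept their calls when any lane was left out.

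**Figure D2:**
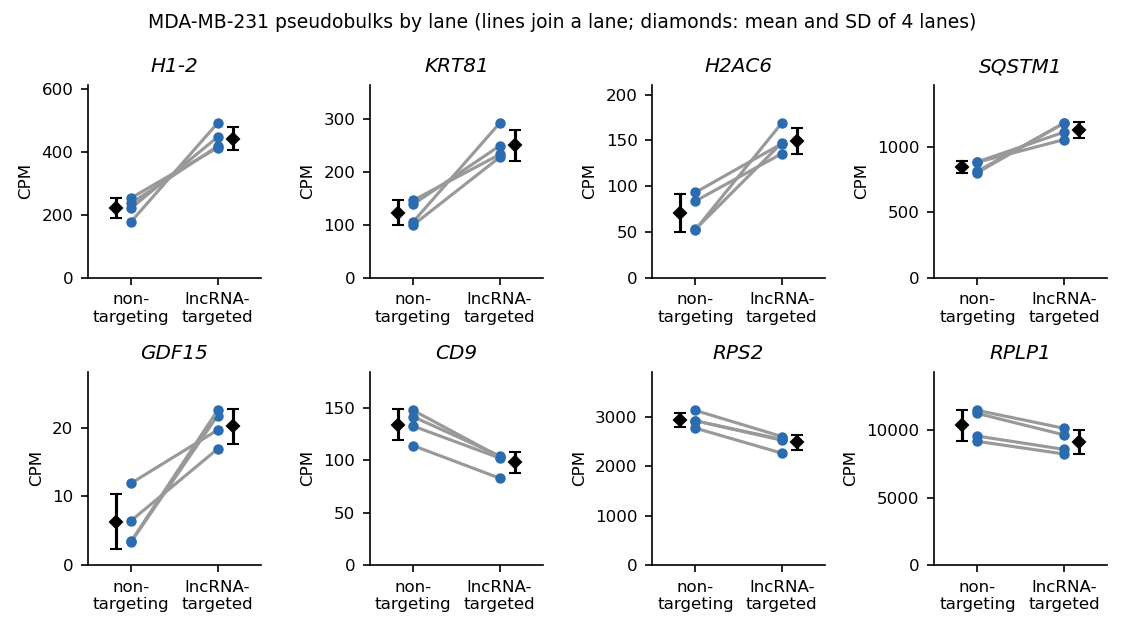
CPM per lane of genes called in lncRNA-targeted against non-targeting MDA-MB-231 cells. Each point is 1 lane, lines join a lane, and diamonds with bars are the mean and SD of 4 lanes.

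Members of the integrated stress response list, which ATF4 drives when translation or amino acid supply is disturbed, rose in the same MDA-MB-231 cells: 22 of 25 were above 0 (median log2 0.18, adjusted p = 0.00127 by fry and BH). NUPR1 (0.77 ± 0.13), DDIT4 (0.45 ± 0.08), SLC3A2 (0.28 ± 0.05) and DDIT3 (0.41 ± 0.08) were called in it. That list had adjusted p = 0.0866 with an estimated correlation. Mitotic genes of the G2M list fell (54 genes, median −0.13, adjusted p = 0.0201; 0.0866 with an estimated correlation), with NUSAP1 (−0.24 ± 0.04), BIRC5 (−0.31 ± 0.06), DLGAP5 (−0.27 ± 0.05) and CKS2 (−0.20 ± 0.05) among 12 called. All 30 proteasome genes were below 0 (median −0.11, adjusted p = 0.0402; 0.124 with an estimated correlation), among them PSMD2 (−0.20 ± 0.05) and PSMC5 (−0.21 ± 0.05). Ribosomal protein genes fell as a list (75 genes, 74 below 0, 40 called lower, median −0.11, adjusted p = 0.0406; 0.124 with an estimated correlation). Splicing factors fell too (median −0.09, adjusted p = 0.0245; 0.124 with an estimated correlation), led by HNRNPD (−0.21 ± 0.05), HNRNPC (−0.17 ± 0.04), SRSF7 (−0.21 ± 0.05) and SNRPD2 (−0.13 ± 0.03).

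Heat shock genes fell (median −0.11, adjusted p = 0.0406 by fry and BH; 0.124 with an estimated correlation), including the chaperone genes HSP90AA1 (−0.18 ± 0.03), HSPE1 (−0.18 ± 0.04) and HSP90AB1 (−0.11 ± 0.03). Nuclear-encoded respiratory chain genes fell (median −0.09, adjusted p = 0.0495; 0.173 with an estimated correlation), including ATP5F1D (−0.22 ± 0.04), UQCRQ (−0.17 ± 0.03), CYC1 (−0.19 ± 0.05) and NDUFB2 (−0.15 ± 0.04). Translation factors (median −0.07, adjusted p = 0.0402; 0.128 with an estimated correlation; EEF1D, EEF1B2 −0.12 ± 0.03) and hypoxia and glycolysis genes (median −0.06, adjusted p = 0.0402; 0.219 with an estimated correlation; LDHA −0.16 ± 0.04) were the remaining lists of the 9 called. Fry tests whether a list moves on balance and makes no comparison with other genes. With no replicate block, only the integrated stress list (adjusted p = 0.000615) and splicing factors (0.0479) passed fry and BH. Leaving out lane 1, 2, 3 or 4 left 1, 3, 1 or 1 lists. The histone list was not called (median 0.12, adjusted p = 0.116) although 5 of its 13 genes were.

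**Figure D3:**
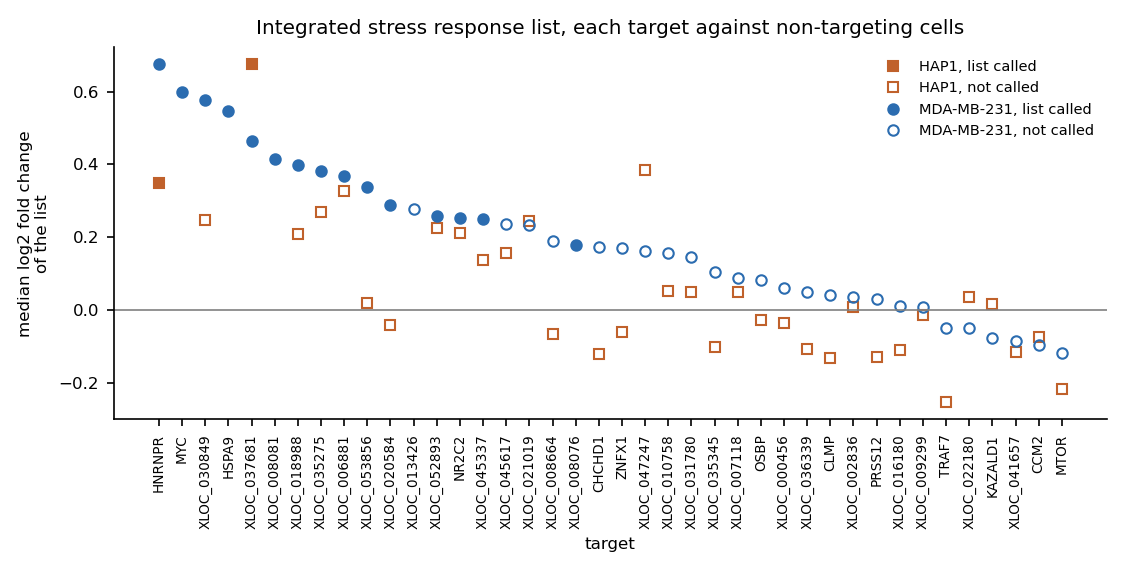
Median log2 fold change of the integrated stress response list for each target against non-targeting cells, in both lines. Filled points were called with fry and BH, and targets are ordered by their MDA-MB-231 median.

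HAP1 gave few calls with lncRNA-targeting arrays. The cartilage matrix gene MATN1 (chr1:30711277-30723585) rose by 2.04 ± 0.25 log2 units (14.9 ± 12.3 against 3.55 ± 4.28 CPM, n = 4 lanes, higher in 4 of 4, adjusted p = 1.78e-05 by edgeR and BH, 0.0356 by DESeq2). It was the 1 gene called of 10747, with 0 lower. Not called were ENSG00000287839 (0.77 ± 0.15, adjusted p = 0.0756), the genome maintenance gene RMI1 (0.83 ± 0.18, 0.0878), the X inactivation regulator FTX (0.38 ± 0.09, 0.218) and the pyrophosphate transporter gene ANKH (1.12 ± 0.29, 0.363). Nor were TPM2 (−0.20 ± 0.04, adjusted p = 0.0843 by edgeR and BH), REL-DT (−0.85 ± 0.18), COX20 (−0.27 ± 0.06), the nuclear lncRNA MALAT1 (−0.15 ± 0.03) and the topoisomerase gene TOP2A (−0.22 ± 0.05), the last 4 at 0.0878. At unadjusted p under 0.05 edgeR gave 592 genes, and DESeq2 called 1 gene after BH. With no replicate block the count was 0. Lane 6 held 54 cells, and without it 32 genes were called. Without lanes 5, 7 and 8 the counts were 0, 3 and 3. No list was called with fry and BH in this comparison (5 at unadjusted p under 0.05, 0 by camera with an estimated correlation, 5 by camera with the preset correlation, 1 without lane 6).

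The response to lncRNA-targeting arrays differed between the lines for named genes. MALAT1 had the smallest p (HAP1 minus MDA-MB-231 −0.48 ± 0.05; −0.15 in HAP1, 0.26 in MDA-MB-231, adjusted p = 2.81e-08 by edgeR and BH). The metastasis-linked calcium-binding protein gene S100A4 (−0.73 ± 0.10; −0.22 and 0.44), SQSTM1 (−0.53 ± 0.09; −0.05 and 0.42) and SNHG25 (−0.46 ± 0.08; −0.01 and 0.40) also differed. CALM2 (−0.26 ± 0.05), NQO1 (−0.43 ± 0.09), MT-ND3 (−0.22 ± 0.05), S100A6 (−0.26 ± 0.06), CD9 (0.56 ± 0.13) and COX20 (−0.32 ± 0.07) passed with adjusted p from 0.0110 to 0.0283. In all, 6 genes had a higher and 19 a lower response in HAP1 of 11940.00 tested with edgeR and BH (755 at unadjusted p under 0.05, DESeq2 4 and 6). The joint fit had a median log2 of −0.0455 over all genes, so its differences lie lower than those of the separate fits. With normalization factors computed within each line, an alternative added later, the median was 0.00827 and 10 higher and 12 lower genes were called. MALAT1 (−0.42), S100A4 (−0.68), SQSTM1 (−0.47), SNHG25 (−0.41) and CD9 (0.61) kept their calls there, and CALM2 (−0.21), NQO1 (−0.38), MT-ND3 (−0.16), S100A6 (−0.20) and COX20 (−0.27) lost theirs. Without HAP1 lane 6 the count was 42 and without lane 7 it was 14. The first 4 genes kept their calls in 12 alternative settings, and each of the last 6 lost its call when at least 4 of the 8 lanes were left out in turn. CD9 lost it without lanes 1, 2, 3, 7 and 8 (0.53 to 0.57), NQO1 without 5 to 8 (−0.35 to −0.43), CALM2 without 2 and 4 to 8 (−0.17 to −0.26), and S100A6 without the same lanes (−0.16 to −0.27). COX20 lost it without lanes 2, 3 and 5 to 8 (−0.24 to −0.31) and MT-ND3 without any lane but 3 (−0.11 to −0.24).

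With arrays against the common essential genes in MDA-MB-231, the nuclear lncRNA MALAT1 was higher (0.68 ± 0.05, 4394 ± 436 against 2746 ± 168 CPM). The nuclear lncRNA NEAT1 (0.85 ± 0.11) and the snoRNA host gene GAS5 (0.72 ± 0.08), a growth arrest transcript, were higher too. Each rose in 4 of 4 lanes. So did the metabolic brake TXNIP (1.42 ± 0.16; 77.7 ± 16.2 against 28.9 ± 6.32 CPM), GDF15 (2.44 ± 0.28; 35.6 ± 17.4 against 6.36 ± 4.07 CPM), SQSTM1 (0.75 ± 0.06), KRT81 (0.96 ± 0.09), KRT7 (0.81 ± 0.10), TSC22D1 (1.01 ± 0.11), AMIGO2 (1.14 ± 0.16), PTPRM (0.75 ± 0.09) and the metallothionein gene MT1E (0.41 ± 0.05). OTULINL fell most (−1.92 ± 0.23, 11.5 ± 3.27 against 43.4 ± 2.15 CPM). APRT (−0.56 ± 0.07), LDHA (−0.50 ± 0.08, 269 ± 31.2 against 379 ± 33.1 CPM) and G0S2 (−0.52 ± 0.07) were also lower. H2AZ1 (−0.41 ± 0.05), SLIRP (−0.43 ± 0.06), RANBP1 (−0.50 ± 0.07), HSP90AA1 (−0.34 ± 0.05), RPL35 (−0.29 ± 0.05), MRPL52 (−0.36 ± 0.06), ZC3H3 (−0.59 ± 0.10) and C1QBP (−0.38 ± 0.06) fell too. Adjusted p was 3.67e-05 or less for all 24 genes by edgeR and BH, and all kept their calls when any lane was left out. The median mitochondrial share of UMIs was 1.31% in these cells against 1.18%. Of 8152 genes 218 were called higher and 266 lower (1562 at unadjusted p under 0.05, DESeq2 45 and 117). The count was 137 with no replicate block, and without lane 1, 2 or 3 the counts were 271, 220.0 and 228.

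In the same MDA-MB-231 comparison fry and BH called 10 lists, each lost with an estimated correlation. Nuclear lncRNAs rose (median 0.25, adjusted p = 0.0435; 0.167 with an estimated correlation), as did matrix and mesenchymal genes (0.26, 0.0435; 0.167) such as TPM1 (0.45 ± 0.08), COL6A1 (0.71 ± 0.16), TGFBI (1.14 ± 0.30) and CD44 (0.33 ± 0.10). Markers of the line (0.15, 0.0354; 0.191), interferon genes (0.35, 0.0354; 0.280) and p53 targets (0.11, 0.0354; 0.610) rose, the last with GDF15 up and the apoptosis gene BAX down (−0.33). Proteasome genes (−0.24, 0.0354; 0.167), ribosome biogenesis genes (−0.10, 0.0411; 0.167), splicing factors (−0.09, 0.0354; 0.167), heat shock genes (−0.18, 0.0435; 0.191) and respiratory chain genes (−0.13, 0.0435; 0.209) fell.

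In HAP1 the positive-control arrays were those against MTOR in 65 of 95 cells. RPL13A (0.27 ± 0.04; 2706 ± 115 against 2254 ± 194 CPM, n = 3 lanes), the elongation factor gene EEF1A1 (0.24 ± 0.03) and GAS5 (0.66 ± 0.10; 272 ± 67.0 against 176 ± 7.03 CPM) rose. UACA (0.88 ± 0.14; 114 ± 12.4 against 61.4 ± 1.86 CPM), the interferon-induced gene IFITM1 (1.42 ± 0.24), the lncRNA XACT (0.81 ± 0.13), ENSG00000287238 (0.77 ± 0.10), APBA1 (0.84 ± 0.15), the Notch coactivator gene MAML2 (0.71 ± 0.13), GSTP1 (0.24 ± 0.04) and ST6GAL1 (0.51 ± 0.10) rose. The divergent transcript IDH2-DT (−3.20 ± 0.48; 3.27 ± 4.41 against 26.7 ± 8.70 CPM), REL-DT (−1.91 ± 0.38), the metallothionein gene MT1X (−0.48 ± 0.07; 348 ± 48.5 against 483 ± 9.92 CPM), the antiviral tetherin gene BST2 (−0.52 ± 0.10), MRPS34 (−0.39 ± 0.07), H4C3 (−0.25 ± 0.05) and SVIP (−0.52 ± 0.10) fell. The chaperone genes HSP90AA1 (−0.22 ± 0.04), HSPD1 (−0.22 ± 0.04) and CALR (−0.37 ± 0.08) fell, with TOMM5 (−0.35 ± 0.07) and HMGA1 (−0.37 ± 0.08). Adjusted p was 0.00463 or less by edgeR and BH.

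Of 9143 genes in that HAP1 comparison, 59 were called higher and 37 lower with edgeR and BH (888 at unadjusted p under 0.05), and 1 with DESeq2. The count was 24 with no replicate block, and without lane 5 or 7 the counts were 34 and 44. Without lane 5, HSP90AA1 (−0.19), H4C3 (−0.13), HSPD1 (−0.19), TOMM5 (−0.30) and HMGA1 (−0.29) lost their calls. Without lane 7, ST6GAL1 (0.42), SVIP (−0.41), HSPD1 (−0.19) and CALR (−0.31) did, and without lane 8, IFITM1 (1.11). No list was called with fry and BH (lowest adjusted p 0.0922; 9 at unadjusted p under 0.05, 0 by camera with an estimated and 9 with the preset correlation). The response to these arrays differed between the lines at 20 genes by edgeR and BH (13 higher, 7 lower in HAP1, 864 at unadjusted p under 0.05). MALAT1 (HAP1 minus MDA-MB-231 −0.61 ± 0.08) and NEAT1 (−1.14 ± 0.15) had the smallest p.

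Arrays against the 10 other protein-coding genes moved some of the same genes as lncRNA arrays in MDA-MB-231. H1-2 (0.54 ± 0.06; 325 ± 27.1 against 222 ± 31.9 CPM, n = 4 lanes), ENSG00000290032 (0.62 ± 0.07), KRT81 (0.47 ± 0.07), H2AC6 (0.56 ± 0.09), SQSTM1 (0.25 ± 0.04), the muscle ankyrin repeat gene ANKRD1 (0.29 ± 0.05), SNHG25 (0.29 ± 0.05) and KRT7 (0.33 ± 0.07) rose. CD9 (−0.35 ± 0.06) and RPS2 (−0.17 ± 0.04) fell, and TMEM158, MYL12A and PABPN1 were not called (0.0824 each). With edgeR and BH 9 genes were called higher and 2 lower of 11531 (884 at unadjusted p under 0.05; 6 and 2 with DESeq2), 4 with no replicate block, and 20.0 without lane 1. Leaving out lanes took the call from ANKRD1 (0.19 without lane 2), SNHG25 (0.23 without lane 4), CD9 (−0.31 without lane 3), KRT7 (0.30, 0.35 and 0.27 without lanes 1, 2 and 4) and RPS2 (−0.14 to −0.19 without any of the 4). Integrated stress genes rose as a list (median 0.07, adjusted p = 0.0305 by fry and BH; 0.400 with an estimated correlation), with 0 of its 23 genes called. In HAP1, BST2 fell (−0.38 ± 0.07; 188 ± 32.5 against 297 ± 89.0 CPM, adjusted p = 0.0135 by edgeR and BH) as the only call of 10675 genes (549 at unadjusted p under 0.05; 0 with DESeq2 and 0 with no replicate block). Its call was lost without lanes 6, 7 and 8 (−0.33, −0.36 and −0.39; adjusted p 0.0723, 0.442 and 0.155), and the number of calls was 3, 2, 3 and 2 without lanes 5 to 8. MATN1 (1.62 ± 0.33) and LIPH (−1.06 ± 0.22), both at 0.0592, MFSD2B (0.48 ± 0.11), RMI1 (0.78 ± 0.19), ADAMTSL1 (0.89 ± 0.22), DLGAP1 (0.25 ± 0.06), ADGRL1-AS1 (−0.63 ± 0.14), DENND1A (−0.42 ± 0.09) and EMG1 (−0.32 ± 0.08) were not called there, and fry and BH called 0 lists (3 at unadjusted p under 0.05, 0 by camera with an estimated and 5 with the preset correlation).

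In MYC-targeted MDA-MB-231 cells (30 cells) TXNIP (2.54 ± 0.27, 169 ± 83.9 against 29.2 ± 6.41 CPM) and the histone gene H4C8 (3.00 ± 0.41) rose. RPLP1 (−0.52 ± 0.08), RPL41 (−0.54 ± 0.08), HSP90AA1 (−0.62 ± 0.10) and the nuclear transport gene RANBP1 (−0.82 ± 0.15) fell. The stress factor gene ATF3 (3.74 ± 0.46) and CHMP1B (2.39 ± 0.30) were also called, each higher in 3 of 4 lanes, and ATF3 lost its call without lane 3 (2.34). In MTOR-targeted MDA-MB-231 cells (88 cells) ANKRD28 (0.96 ± 0.15), NEAT1 (1.03 ± 0.17), TPM1 (0.67 ± 0.11) and the growth factor receptor gene EGFR (0.80 ± 0.14) rose. LDHA (−0.57 ± 0.11), RAB5IF (−0.55 ± 0.11), DYNLT1 (−0.60 ± 0.13) and UQCR10 (−0.41 ± 0.09) fell. DYNLT1 lost its call without lane 1 (−0.53) or 2 (−0.52) and UQCR10 without lane 3 (−0.37). Adjusted p was 0.00239 or less by edgeR and BH for these genes.

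Among lncRNA targets in MDA-MB-231, XLOC_035275 (147 cells) raised H2AC6 (1.88 ± 0.21; 269.9 ± 59.2 against 71.9 ± 21.3 CPM), KRT81 (1.79 ± 0.22), H1-2 (1.64 ± 0.20) and KRT7 (1.09 ± 0.15), and lowered CD9 (−0.79 ± 0.14), PDAP1 (−0.62 ± 0.11), SELENOH (−0.46 ± 0.10) and TMBIM4 (−0.86 ± 0.18; −0.74 and not called without lane 4). XLOC_030849 (54 cells) raised KRT81 (2.28 ± 0.25; 639 ± 393 against 125 ± 23.5 CPM), the MTOR inhibitor gene DDIT4 (1.69 ± 0.21), TXNIP (1.99 ± 0.26) and ENSG00000223786 (5.03 ± 0.63), and lowered CD9 (−1.29 ± 0.21), EIF3K (−0.67 ± 0.12), PDAP1 (−0.84 ± 0.16) and HSP90AA1 (−0.51 ± 0.10). XLOC_037681 (55 cells) raised the snoRNA host genes GAS5 (1.30 ± 0.16; 773 ± 162 against 313 ± 29.9 CPM) and SNHG25 (1.16 ± 0.15) and the lncRNA CYTOR (0.95 ± 0.11). It lowered the DNA repair kinase gene PRKDC (−0.72 ± 0.13), the spindle gene NUSAP1 (−0.95 ± 0.17), PDAP1 (−0.80 ± 0.15) and KTN1 (−0.45 ± 0.09). ENSG00000274213 (2.04 ± 0.31) was called with it but not without lane 4 (0.98). XLOC_008076 (37 cells) raised TXNIP (2.15 ± 0.28), H4C8 (3.00 ± 0.40) and ENSG00000290032 (1.86 ± 0.25) and lowered the mesenchymal filament gene VIM (−0.42 ± 0.08), NDUFA11 (−0.49 ± 0.10), UQCRQ (−0.50 ± 0.10) and PHPT1 (−0.77 ± 0.15; not called without lanes 2 and 4, −0.61 and −0.64). The interferon-induced gene ISG15 (2.93 ± 0.30; 936 ± 1630.05 against 90.5 ± 19.7 CPM) was called with it, but fell to 0.48 without lane 1. UMIs per cell were lower than in non-targeting cells in 4 of 4 lanes with XLOC_030849 (log2 −0.34), XLOC_035275 (−0.20) and XLOC_037681 (−0.18), and in 2 of 4 with XLOC_008076 (−0.18). Adjusted p was 0.00113 or less by edgeR and BH.

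Across the 40 targets in MDA-MB-231 edgeR and BH within each target gave 966 higher and 676 lower calls, 1259 and 400 with DESeq2 size factors, and 1573 and 605 with DESeq2. Adjusted over all targets together the total was 988. It was 937 in place of 1642 with no replicate block, and without lane 1, 2, 3 or 4 it was 914, 1006, 869 or 881. At least 5 genes were called for 21 targets, among them 14 of the 27 lncRNAs, and 8 lncRNA targets had 0. The largest counts were 232 (MYC), 220.0 (MTOR), 167 (XLOC_008076), 166 (XLOC_035275), 139 (XLOC_030849) and 129 (XLOC_037681). The histone gene H1-2 and ENSG00000290032 were called higher with 15 lncRNA targets each, H2AC6 with 13, KRT81 with 12, KRT7 with 10, NQO1 and SNHG25 with 9, and DDIT4, GDF15, H4C8 and NUPR1 with 8. RPS2 was called lower with 9, PDAP1 with 7 and CD9 with 6. In all 97 genes were called with 3 or more lncRNA targets, where 1.80 would be expected from independent lists. Shared controls enter this count: 32 genes had 5 or more targets with all non-targeting arrays, 38 with the most abundant array alone, 21 with the other arrays, and 18 in all of these.

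**Figure D4:**
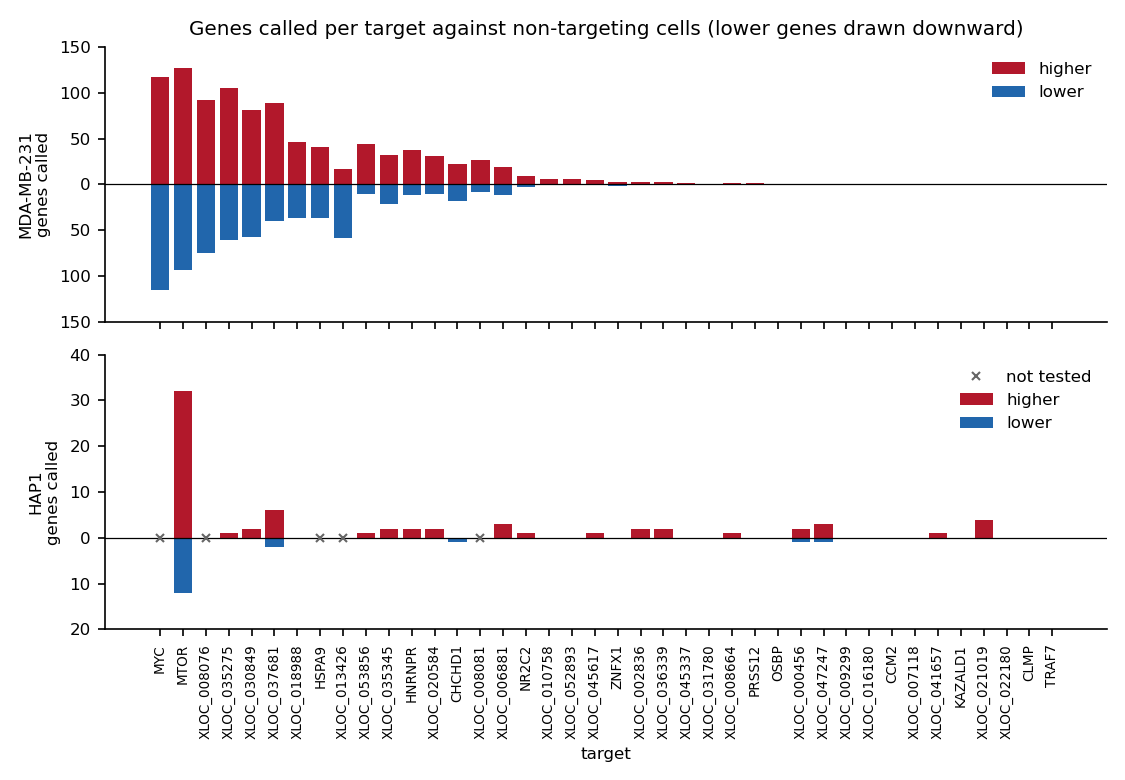
Genes called per target against non-targeting cells in both lines, edgeR with BH within each target. Targets are ordered by their number of calls in MDA-MB-231, and crosses mark targets not tested in HAP1.

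In HAP1 the MTOR arrays (65 cells) gave the clearest single-target response. UACA (1.21 ± 0.18; 148 ± 23.0 against 63.3 ± 2.04 CPM, n = 3 lanes), MAML2 (1.08 ± 0.21), the glypican gene GPC4 (1.10 ± 0.22) and IFITM1 (1.86 ± 0.39) rose, and TOMM5 (−0.50 ± 0.11), MRPS34 (−0.49 ± 0.11), CALR (−0.47 ± 0.11) and MTOR itself fell. Of these only UACA kept its call without any of the lanes: MAML2 lost it without lane 7 or 8 (0.99, 1.15), GPC4 without 5 or 8 (1.07, 1.01), IFITM1 without 7 or 8 (1.73, 1.57), MRPS34 without 7 or 8 (−0.56, −0.38), MTOR without 7 or 8 (−1.06, −1.24), and TOMM5 and CALR without 5, 7 or 8 (TOMM5 −0.49, −0.55, −0.50; CALR −0.59, −0.42, −0.43). XLOC_037681 (21 cells) raised DDIT4 (3.04 ± 0.53; 81.6 ± 39.8 against 8.24 ± 3.21 CPM), GAS5 (1.03 ± 0.20), ENSG00000287839 (2.30 ± 0.34) and PARP16 (3.00 ± 0.49, higher in 2 of 3 lanes), and lowered CHCHD10 (−0.65 ± 0.13) and ELP5 (−0.88 ± 0.20). Without lane 5, 7 or 8 the XLOC_037681 cells fell under 20, so its calls were not tested that way. Adjusted p ran from 2.95e-06 to 0.0389 by edgeR and BH.

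Other HAP1 targets had 4 calls or fewer, and most of these genes lost their calls when 1 lane was left out. With XLOC_047247 the mitochondrial protein gene C1QBP fell (−0.40 ± 0.08; −0.43, −0.34 and −0.39 and not called without lanes 5, 6 and 7), and ENSG00000289084 (3.62 ± 0.50), ENSG00000223725 (6.21 ± 0.86) and the pseudogene PKD1L2 (5.22 ± 1.05) were called higher. Without lane 5 the first pair lost their calls (1.51 and 4.61), and PKD1L2 did without lane 6 (2.48). With XLOC_021019 PKD1L2 was higher in 1 of 3 lanes (5.89 ± 0.99) and −1.58 without lane 5. MB21D2 (1.64 ± 0.29; 0.37 without lane 7), ENSG00000259589 (2.69 ± 0.55; 2.83 and 2.03 without lanes 5 and 8) and ENSG00000255476 (3.19 ± 0.67; 2.69 without lane 7) lost theirs in the same way. With XLOC_006881 the sialic acid gene GNE (2.05 ± 0.35; 1.52 without lane 8), KLHL21 (2.52 ± 0.50; 1.14 without lane 8) and ENSG00000287839 (1.45 ± 0.32; 1.40 to 1.52 without lanes 5, 7 and 8) did. With XLOC_000456 the developmental factor gene EYA1 (2.79 ± 0.56; 0.76 without lane 7), ITGA9 (2.40 ± 0.49; 1.88 and 1.82 without lanes 5 and 6) and TTC9C (−1.96 ± 0.43; −1.64 to −1.95 without lanes 6, 7 and 8) did. Over 35 HAP1 targets and 8060.0 genes edgeR and BH gave 68 higher and 17 lower calls, 50.0 with no replicate block, and 37 when adjusted over all targets together. Leaving out lane 5, 7 or 8 gave 39, 36 or 38, over the 33, 31 or 30.0 targets that still had enough cells. Of 24 lncRNA targets 9 had 0 calls, and only MTOR (44) and XLOC_037681 (8) had 5 or more.

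Integrated stress genes rose with 15 MDA-MB-231 targets, 11 of them lncRNAs (fry, BH over 1040.0 target-list pairs), and 10 of the 15 held with an estimated correlation. XLOC_030849 (median log2 0.58, adjusted p = 3.60e-11) and HNRNPR (0.68, 1.40e-09) had the smallest p. In XLOC_035275-targeted cells DDIT4 (1.03 ± 0.17), NUPR1 (1.57 ± 0.28) and the amino acid transporter gene SLC7A5 (0.60 ± 0.16) carried it (0.38, 8.32e-06). Nuclear lncRNAs rose with 14 targets (2 held with an estimated correlation), markers of the line with 11 (5 held), histones with 7 (2 held), luminal genes with 6 (3 held), and interferon (0 held), mitochondrially encoded (0 held) and matrix genes (1 held) with 5 each. Proteasome genes fell with 13 targets (2 held), splicing factors with 11 (1 held), translation factors with 8 (0 held), heat shock genes with 7 (1 held), ribosome biogenesis with 6 (0 held), ribosomal proteins with 4 (0 held), and S phase, hypoxia and respiratory chain genes with 2 each (0 held). P53 targets and immediate early genes rose with 1 target each, and unfolded protein response genes fell with 1 (0 held). Apoptosis, G2M, cholesterol, NF-kB and HAP1 marker lists had 0 calls. In all 126 pairs were called, 80.0 with no replicate block, and without lane 1, 3 or 4 the count was 83, 72 or 54.

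In HAP1 5 of 910.0 target-list pairs were called with fry and BH. Integrated stress genes rose with XLOC_037681 arrays (median 0.68, adjusted p = 0.000274 by fry and BH, 0.00585 by camera with an estimated correlation). They also rose with HNRNPR arrays (0.35, 0.0146 and 0.0646 by the same tests). With MTOR arrays ribosome biogenesis genes such as DDX21 fell (−0.22 for the list, 0.00116 and 0.0115 by the same tests). Heat shock genes (−0.25, 0.00768 and 0.0392) and proteasome genes (−0.18, 0.0280 and 0.205) fell too. With no replicate block 1 pair was called, XLOC_037681 with integrated stress genes (0.000461), and without lane 5, 7 or 8, where XLOC_037681 was not tested, the count was 1, 0 or 2.

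MTOR (r = 0.230), XLOC_035275 (0.222), XLOC_037681 (0.138), XLOC_008664 (0.136), CHCHD1 (0.101), CLMP (0.0687), XLOC_000456 (0.0552) and XLOC_022180 (0.0411) resembled themselves across the lines more than any other target did. These 8 were 3 without HAP1 lane 7, and 5 with Spearman correlation, with genes of at least 100.0 CPM or without MDA-MB-231 lane 4. Over 35 targets and 6461 genes the mean correlation of log2 fold changes was 0.0575 for the same target and 0.0333 for mismatched targets. The permutation p was 1e-05, for the upper tail only and the smallest possible. The lines share no control cells, so shared controls do not enter this comparison. The correlations were small, and targets in each line shared their controls among themselves.

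More MDA-MB-231 cells were scored as G1 with lncRNA-targeting arrays. The G1 share was 12.6 ± 1.84% against 6.85 ± 2.03% in non-targeting cells and the G2M share 69.5 ± 3.52% against 77.7 ± 3.73%, in the same direction in 4 of 4 lanes (exact two-sided paired permutation p of 1 in 8, the smallest possible with 4 lanes), and unthinned the G1 shares were 11.2% and 4.67%. Positive-control cells had a G1 share of 27.5 ± 7.59%, and other protein-coding targets 9.43%. In HAP1 the shares of lncRNA-targeted and non-targeting cells were 1.43% and 0.301% in G1, 22.7% and 23.6% in S, and 75.9% and 76.1% in G2M. Unthinned, the HAP1 G2M shares were 94.1% and 95.3%, so the size of these shares depends on the scoring. G2M genes took 0.730% of UMIs against 0.768% in MDA-MB-231 (lower in 3 of 4 lanes, exact two-sided paired permutation p of 1 in 4) and 0.598% against 0.655% in HAP1 (lower in 4 of 4, the smallest possible p). No change of cycling is read from the phase calls. UMIs per cell were lower with positive-control arrays in HAP1 (log2 −0.300, exact permutation over 5 and 9 arrays, two-sided p = 0.00200) and with lncRNA arrays in MDA-MB-231 (−0.115, permutation p = 0.0428 over 80 and 9 arrays). Each array's median was taken over cells of all lanes together. Lane medians ran from 18213.5 to 44152.5 UMIs in HAP1, so the lanes an array's cells came from can enter these differences. The other 4 comparisons gave −0.0890 for lncRNA arrays in HAP1 (p = 0.211), −0.213 for positive controls in MDA-MB-231 (exact permutation p = 0.0667), and −0.0476 and −0.0618 for other protein-coding targets in HAP1 (permutation p = 0.480) and MDA-MB-231 (0.142). Cells per target correlated between the lines (Pearson r = 0.931, Spearman rho = 0.932, 40 targets), and with the Fisher exact test and BH 0 of 40 targets differed in share (7 at unadjusted p under 0.05, XLOC_045617 lowest at 0.00247, adjusted 0.0989).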

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

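The rules that single out a value (far from the other lanes, or different between the lines) were fixed before the results were seen. The tests of other protein-coding targets, and of the difference between the lines with factors computed within each line, were chosen afterwards.

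Lane 6 of HAP1 held 2128119 UMIs, far under the other lanes of that line, because it held 54 cells. Median genes per cell in lane 4 of MDA-MB-231 (4032.5) lay under the other lanes. The G1 share of non-targeting cells reached 1.20% in 1 HAP1 lane, and that of lncRNA-targeted cells 3.13% in 1 HAP1 lane. BST2 had a log2 fold change of −1.57 in 1 HAP1 lane with other protein-coding targets, and KRT81 one of 1.34 in 1 MDA-MB-231 lane with positive-control arrays. Of 93 groups of lanes searched in this way, 6 held such a value, and about 1 in 20 would by chance.

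The response differed between the lines at 25 genes for lncRNA arrays and at 20 genes for positive-control arrays (edgeR, BH). For lncRNA arrays the differences, HAP1 minus MDA-MB-231, were −0.48 for MALAT1, −0.73 for S100A4, −0.53 for SQSTM1, −0.46 for SNHG25, −0.26 for CALM2, −0.43 for NQO1, −0.22 for MT-ND3, −0.26 for S100A6, 0.56 for CD9 and −0.32 for COX20. With factors computed within each line CALM2, NQO1, MT-ND3, S100A6 and COX20 lost their calls (−0.21, −0.38, −0.16, −0.20 and −0.27). H1-2 (−1.04 ± 0.12) and H2AC6 (−1.03) were called as well but were not among the named genes. Against non-targeting cells H2AC6 was higher in all 4 lanes of each line. H1-2 was higher in 4 MDA-MB-231 lanes and in 2 HAP1 lanes, with 2 lower. Of the named genes, SQSTM1, SNHG25 and NQO1 were also higher in 2 HAP1 lanes and lower in 2.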

How the results depend on the processing

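Controls restricted to part of the non-targeting arrays and the settings for other protein-coding targets and for the difference between the lines were added after the first results; the other settings, and the tests, lists and naming rule, were chosen before the data were examined. The cause of these changes was not tested. Counts are genes called unless stated.

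For lncRNA arrays in HAP1 the count of 1 was 37 with no expression filter, 0 with no replicate block, 0 with each array as a unit, 3 against the most abundant non-targeting array and 2 against the 9 others, and 0 to 32 with a lane left out (32 without lane 6). In MDA-MB-231 the 334 were 29 with no replicate block, 3 with each array as a unit, 207 against the most abundant non-targeting array, 82 against the others, and 179 to 213 with a lane left out. All 29 calls of the fit with no block, and the 3 with each array as a unit, were among the 334.

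For positive controls in HAP1 the 96 were 1 with DESeq2, 170.0 unfiltered, 24 with no replicate block, 2 by array and 34 to 106 with a lane left out. In MDA-MB-231 the 484 were 162 with DESeq2, 137 with no replicate block, 159 by array and 220.0 to 392 with a lane left out. For other protein-coding targets in HAP1 the 1 was 3 with DESeq2 size factors, 0 with DESeq2, 31 unfiltered, 5 with stricter assignment, 0 with no replicate block, 0 by array and 2 to 3 with a lane left out. In MDA-MB-231 the 11 were 33 unfiltered, 4 with no replicate block, 0 by array and 11 to 20.0 with a lane left out.

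Summed over single targets, the 85 in HAP1 were 493 unfiltered, 50.0 with no replicate block, 26 with non-targeting cells thinned, 275 with a fit per target, 32 against the most abundant non-targeting array and 36 to 82 with a lane left out. The 1642 in MDA-MB-231 were 3942 unfiltered, 937 with no replicate block, 787 by array, 1008 with non-targeting cells thinned and 869 to 1006 with a lane left out.

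For lncRNA arrays 0 lists in HAP1 were 5 with preset camera and 0 to 1 with a lane left out. The 9 in MDA-MB-231 were 15 with preset camera, 0 with an estimated correlation, 2 with no replicate block and 1 to 3 with a lane left out. Target-list pairs were 5 in HAP1 (113 preset, 3 estimated, 1 with no replicate block, 0 to 6 with a lane left out) and 126 in MDA-MB-231 (310.0 preset, 27 estimated, 80.0 with no replicate block, 54 to 100.0 with a lane left out). The difference between the lines, 25, was 22 with factors computed within each line, 10.0 with DESeq2, 114 unfiltered and 14 to 42 with a lane left out. The S phase difference of −0.848 points in HAP1 was 0.976 unthinned and 0.0150 as a share of UMIs, and 2.54 in MDA-MB-231 was −0.00410 as a share of UMIs.

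Named genes gave 2394 alternative values for 215 results, of which 2092 kept their call, 301 lost it and 1 reversed: PKD1L2 with XLOC_021019 in HAP1 (−1.58 without lane 5, and up to 6.93 without lane 7). The unblocked fit lost 45, the fit by array 59 and DESeq2 47. The own RNA of MTOR in HAP1 was weaker by array (−1.08) and without lane 7 (−1.06) or 8 (−1.24), and that of HNRNPR in MDA-MB-231 without lanes 1, 2 and 3 (−0.64, −0.70, −0.63). Genes near the targeted lncRNAs were not tested, as their positions were not used here, and the quality filter removed no cell.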

Other observations

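Tests of matched UMIs, of target abundance, of cell numbers and of genes fallen in both lines were written before the results they concern, and the tests of non-targeting arrays, of any targeting array, of splits and of nearness to a coding target were chosen after seeing results.

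The 334 genes called with lncRNA arrays in MDA-MB-231 were weighed against 4 explanations. Against the 9 other non-targeting arrays the folds had a slope of 0.851 (0.664 to 1.12) on those against the most abundant array. Both sets of folds share the lncRNA-targeted sums, and the genes were called against all arrays together. This raises the slope, so it does not by itself rule out a property of that array. With UMIs per cell matched the slope was 0.957 (0.934 to 0.975), and 75 genes were called higher and 222 lower. The 1513 matched cells were drawn from the same lncRNA-targeted cells and set against the same non-targeting cells. The genes had been called without matching. This also raises the slope, so the slope does not by itself rule out lower UMI counts as a cause. Folds with arrays against other protein-coding genes had a slope of 0.458 (0.349 to 0.576) on those with lncRNA arrays, with controls split between the comparisons. Both parts of the controls had entered the calls of these genes, which can raise this slope despite the split. Part of the response could be shared with targeting arrays against other genes. It was not alike with all of them: response scores were 0.338 for CHCHD1 and 0.319 for HNRNPR, and 0.00269 for PRSS12 and 0.0256 for TRAF7. Over 13 protein-coding targets the response rose with the CPM of the target (Spearman rho = 0.753, permutation p = 0.00411). Over the 10 that are not positive controls rho was 0.709 (permutation p = 0.0266). In HAP1 rho was −0.0228 over 11 protein-coding targets (permutation p = 0.951). Scores were taken over 322 genes in MDA-MB-231 and 283 in HAP1. The HAP1 scores of these targets lay only between −0.0629 (TRAF7) and 0.0774 (ZNFX1). With so little response there, the HAP1 value is not a like test of the relation. Stronger cleavage of abundant RNAs could give the relation in MDA-MB-231. The 2 highest scores there among protein-coding targets were those of HSPA9 (0.430) and MYC (0.374), essential genes whose own RNA was not lower (0.05 and 0.46). An RNA cut upstream can still be counted, so those values do not show that cleavage was absent. The cause stays open.

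Fewer genes were called per target in HAP1 (85) than in MDA-MB-231 (1642). MDA-MB-231 cells drawn down to the HAP1 number per lane and target still gave 302 to 537 calls in 4 draws, over 35 targets in place of 40. Fewer cells therefore cannot account for the whole difference.

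Non-coding genes called lower with an lncRNA target may be the targeted transcripts or lie beside them, which the library names do not say. SLCO4A1-AS1 (chr20:62663027-62666621) fell with XLOC_031780 (−1.37 ± 0.18, adjusted p = 1.84e-08 by edgeR and BH) as that target's 1 call, ZFAS1 with XLOC_030849 (−0.59 ± 0.16), SNHG19 with XLOC_018988 (−0.89 ± 0.25) and ZDHHC12-DT with XLOC_020584 (−1.16 ± 0.25). SNHG8 (chr4:118278762-118279823) fell with XLOC_037681 in MDA-MB-231 (−0.59 ± 0.16) and had unadjusted p = 0.000154 by edgeR in HAP1 (−0.74 ± 0.19). Thus 1 target had a non-coding gene lower in both lines at unadjusted p under 0.001, where no mismatched pairing had any (highest 0 of 1000.0). That result rests on 1 gene at a strict threshold, so it weighs little. Of 5 such genes with a position, 3 lay within 100 kb of a protein-coding target of the library (6 of all 251 tested non-coding genes did), namely ZFAS1 121 bp from ZNFX1, SNHG8 215 bp from PRSS12 and SNHG19 424 bp from TRAF7. This nearness was noticed on these same genes, so no p is given for it. With the ZNFX1, PRSS12 and TRAF7 arrays these RNAs did not fall in MDA-MB-231 (0.11, 0.11 and 0.18). Those arrays gave no called fall of ZNFX1 (0.08 ± 0.22) or TRAF7 (−0.35 ± 0.41) there, and PRSS12 was not tested (1 against 28 UMIs). The values of the non-coding RNAs with these arrays therefore decide little. PRSS12 itself was lower with XLOC_037681 in HAP1 (−1.77 ± 0.55, unadjusted p = 0.00147, adjusted p = 0.234 by edgeR and BH), by more than with its own arrays (−0.71 ± 0.39).

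Whether chance could give as many calls was tested by splitting the same sums in other ways. The sums of a lane resemble each other, so the class comparisons were set beside the splits that also part every lane. These number 8 (4 for the HAP1 positive controls), too few for a share under 0.05. The real counts and the highest of the other such splits were 334 and 1 for lncRNA arrays, 484 and 0 for positive controls and 11 and 1 for other protein-coding targets in MDA-MB-231. In HAP1 they were 1 and 4, 96 and 1, and 1 and 4. Splits that leave both sums of a lane on 1 side reached 16, 21 and 14 in MDA-MB-231, and 6, 3 and 9 in HAP1. For the lines (6955 against 0, 1 of 35) and the difference between them (25 against 12, 1 of 35) no other split reached the real count. These shares are under 0.05 and are the smallest that 35 splits can give. With target labels reassigned at random among the cells of each lane, on every 5th gene, the highest other count was 11 in each line. The real counts were 16 in HAP1 and 357 in MDA-MB-231 (1 of 21 each, the smallest share possible). The HAP1 count is not far above the one reached at random. Cells of different arrays were mixed in this way, so chance differences between arrays were not tested.

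Shared controls link the targets of a line. The mean correlation of folds between lncRNA targets was 0.455 with shared and 0.353 with split controls in MDA-MB-231, and 0.195 and 0.0526 in HAP1. The resemblance between targets in HAP1 was therefore mostly lost with split controls, and most of it stayed in MDA-MB-231.

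What separates the lncRNA targets with many calls from the 8 with 0 in MDA-MB-231 stays open here, because the targets' own RNA could not be measured. Over all targets, those with fewer cells had more calls (Spearman rho = −0.420 in MDA-MB-231, −0.446 in HAP1). Lanes that come from separate cultures, and non-targeting arrays in equal numbers, would test the pooled response with independent replicates.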
